A study of Arabidopsis thaliana with 7 samples.

How the data were processed

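RNA from entire rosettes of 14-day-old plants, grown at 70% humidity, 22 degrees by day and 19 by night, with 10 hours of light and 14 of darkness per the labels, was hybridised to 1-colour Affymetrix ATH1 arrays. Genotypes were taken from the source names and treatments from the sample titles. The 7 groups hold 1 array each. The deposited values are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 summarises the probes of a probe set and scales each array to a common trimmed mean. The 2% trimmed means of the 7 deposited arrays lay between 99.96 and 99.97, within the 5% set beforehand, and the intensities were used as deposited. The number of arrays and the signal over background limit the precision.

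Of 22810 probe sets, 64 were controls. Among the other 22746, the platform annotation gave no gene for 8730, several genes for 503 and 1 gene for 13513, of which 13436 matched the gene table of assembly TAIR10.1 by gene number. That table was used for names only. Of several probe sets for a gene, the one with the highest mean signal was kept, leaving 13286 genes. The floor was the mean over arrays of the 40th percentile of signal over non-control probe sets, 22.1. Signals below it were set to it before taking log2.

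With 1 array per group no p-value or standard error was computed. Genes were counted at 2-fold. Each mutant was compared with the wild-type Pst array, and genes were also required, as a second count, to differ at least 2-fold from the median of the other mutant arrays. The double mutant was compared with both singles. Correlations of mutant effects were set beside 100 simulated draws of unchanged arrays sharing the wild-type array, with each gene's SD over the 6 Pst arrays. A second simulation without the wrky60 array was added after seeing the data. Correlations were repeated with no shared array, the second mutant being compared with the mean of the remaining mutant arrays, both ways round. For gene lists, the median log2 ratio of measured members (mean signal at or above the floor) was ranked among 10000 random lists of the same size, drawn with replacement within 20 bins of mean signal. A list stood apart below percentile 2.5 or above 97.5. Random members were drawn independently, so the percentiles take no account of list members that vary together. Of 329 genes in 20 lists, 47 had a named probe set and 38 were measured, so most lists could not be summarised.

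Named genes followed a rule fixed before the data were examined: the targeted genes; the 12 highest and 12 lowest genes of the wild-type response among those at least 2-fold on the same side on all Pst arrays; for each single mutant the 10 highest and 10 lowest, and for the double mutant 12 and 12, among genes passing both counts; up to 4 members of each list; and 5 genes on each side for the double mutant against the more extreme single. Some genes of no known function were left out of the text. Genes with no symbol in the table are given by locus code.

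The functions were tested on simulated data, with a test written after their first use on the arrays. In a simulated comparison of wrky53 with the wild type over 13286 genes, 98.5% of 200 genes changed 4-fold passed both counts, but 38.5% of 200 changed 2-fold, all taken from genes above 4 times the floor, and 24 of 12886 unchanged genes passed. Of 100 random unshifted lists, 9 fell outside the percentile limits, where chance gives 1 in 20. The simulated arrays used each gene's spread over the Pst arrays other than wrky60, which differ in genotype.

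Alternatives fixed beforehand were floors at the 25th and 60th percentile, log2 of signal plus the floor value with no floor, quantile normalization, median centring, cyclic loess (fast method, 3 iterations) on log2 of signal plus 1, every probe set without collapsing, the mean of a gene's probe sets, other comparators, lists with no minimum signal, and Pst-response genes chosen on the wrky60 and wrky53 arrays. Leaving out the wrky60 array, and Pst-response genes chosen on the median of other mutants, were added after seeing the data. A count was treated as moved beyond 1.5 times, a gene beyond 1.5-fold, a correlation beyond 0.1 and a list median beyond the SD of random medians. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.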

Results

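Gene expression was measured on 7 one-colour oligonucleotide arrays, each hybridised with labelled RNA from entire rosettes of 14-day-old Arabidopsis thaliana plants. The title of the series names the group II-A WRKY transcription factors, a family of DNA-binding proteins in plants, and early leaf senescence. Wild-type Col-0 plants were sampled after a MgCl2 mock treatment and after Pst-DC3000, a strain of the bacterial pathogen Pseudomonas syringae that makes the jasmonate mimic coronatine. T-DNA knockout lines of WRKY18, WRKY40, WRKY60 and WRKY53, and a double mutant of WRKY18 and WRKY40, were sampled after Pst-DC3000 only. Each of the 7 groups had 1 array. There was therefore no replicate error, no difference between arrays was tested against one, and none can be separated from the variation between single plants or arrays. The time between treatment and harvest was not given in the sources used here. Signals below a floor of 22.1 were set to it, so that a ratio against such a signal is given as at least that fold. After naming and collapsing probe sets, 13286 genes were compared, of which 7259 had a mean signal at or above the floor.

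The targeted genes were examined first as a check of the labels. WRKY53 had a signal of 3.07 on the wrky53 array, below the floor, against 79.3 to 141 on the other Pst arrays and 358 on the mock array. It was at least 4.85-fold lower on the wrky53 array than on the wild-type Pst array. With a higher alternative floor, which also lies above the signal on the wrky53 array, the log2 ratio was -0.82 or lower. WRKY18, WRKY40 and WRKY60 have no probe set with a single named gene in the annotation used here, so their labels were not checked by their own named transcripts. The position of each insertion relative to the probes is not given in the sources used here.

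The wild type after Pst-DC3000 was compared with the wild type after mock treatment to describe the response to the bacterium. Among genes with higher signals after Pst, AT4G24350 had a 10.4-fold higher signal, TBL26 a 9.59-fold higher signal and JRG21, a jasmonate-regulated gene, an 8.71-fold higher signal. NAI1, a transcription factor required for endoplasmic reticulum bodies, was at least 8.23-fold higher. JMT, which methylates jasmonic acid, was at least 7.34-fold higher, and the plant defensin gene PDF1.2b was 6.24-fold higher. The methionine sulfoxide reductase genes MSRB9 and MSRB6 were 6.79-fold and 5.36-fold higher. Among genes with lower signals, AT1G49000 was 10.2-fold lower, AT1G65490 3.98-fold lower and WRKY53 3.35-fold lower. WRKY47 was 2.62-fold lower, the glutamate receptor gene GLR2.7 at least 2.61-fold lower and the receptor kinase gene AT1G51850 2.56-fold lower.

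In all, 137 genes were at least 2-fold higher and 140 at least 2-fold lower on the wild-type Pst array, and 237 and 230 with the floor at the 25th percentile in place of the 40th. Of these, 62 higher and 24 lower genes lay at least 2-fold on the same side of the mock array on all 6 Pst arrays, which differ in genotype and are not replicates. The named genes above were taken from these 86. For WRKY53 the wrky53 array is that of its own knockout, so its place among them rests on the other Pst arrays. The mock array entered every one of these comparisons, so its own error is shared by all of them. With 6 arrays against 1, an exact permutation test cannot give a one-sided p below 0.143, and none was run.

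The measured genes of the pattern-triggered immunity list, which covers the response to conserved microbial molecules, had lower signals on the wild-type Pst array than on the mock array. Of its 22 members only 6 were measured, among them a receptor gene, a kinase gene and ubiquitin ligase genes. The list median is therefore no measure of pattern recognition. The median log2 ratio of the 6 measured members was -0.87, at percentile 0 of 10000 random lists matched on signal, and all 6 members were below 0, with 1 at least 2-fold lower. Because random members were drawn independently, percentiles here and below can overstate how far a list of genes that vary together stands apart. WRKY22 had a log2 ratio of -1.35, the receptor gene EFR, which was at the floor on the Pst array, -0.98 or lower, the ubiquitin ligase gene PUB22 -0.92 and the kinase gene BIK1 -0.82. The 7 measured photosynthesis genes had a median of -0.18, at percentile 6.76, and the 5 measured reference genes a median of -0.01, at percentile 43.5. Neither of these lists stood apart from random lists by the limits set. Of the lists fixed before the data were examined, these 3 of 20 had at least 3 measured members, a minimum set after the data were seen. The other lists were not summarised, and some of their members are given singly. In the ethylene list, PDF1.2 and PDF1.2b had log2 ratios of 2.34 and 2.64. In the jasmonate list, JMT had a ratio of at least 2.88, and BSMT1, which methylates salicylic acid, was at least 4.59-fold higher. GH3.3, an auxin-conjugating enzyme gene, had a ratio of 1.41, and WES1 (GH3.5) -0.89.

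**Figure D1:**
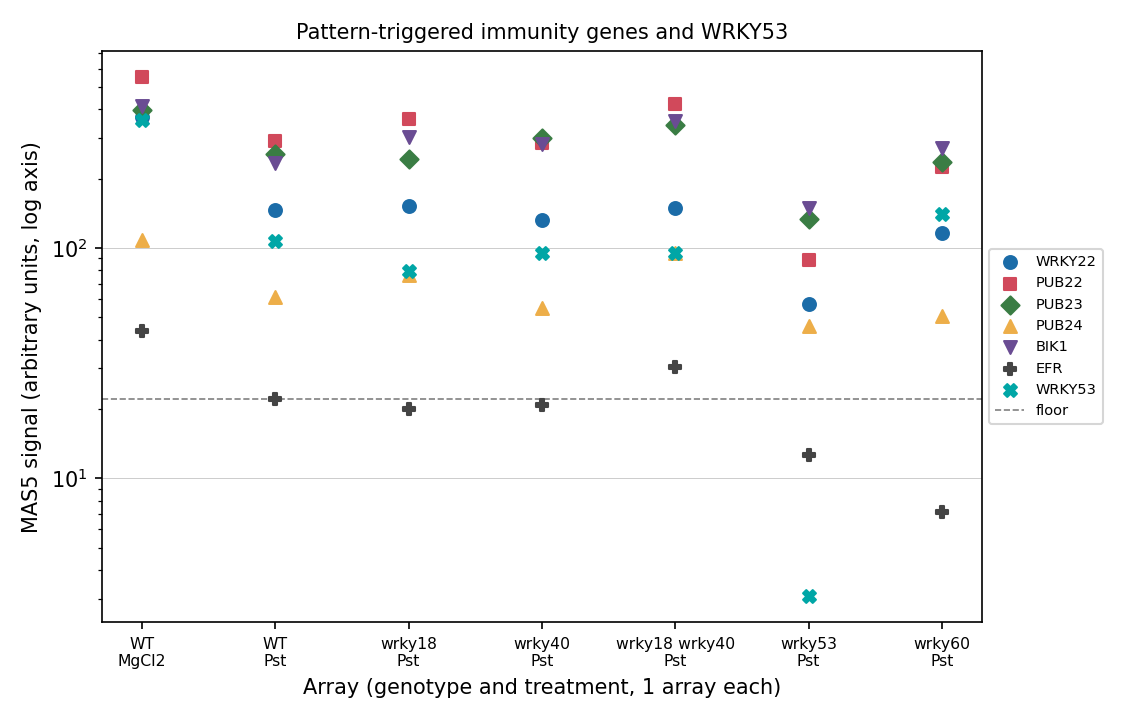
MAS5 signal on a log axis (arbitrary units) of 6 pattern-triggered immunity genes and WRKY53 on each of the 7 arrays, 1 point per gene and array, with the floor of 22.1 as a dashed line. PUB22 had a signal of 552 on the mock array, 292 on the wild-type Pst array, 88.4 on the wrky53 array and 422 on the array of the double mutant.

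The wrky18 and wrky40 single mutants were compared with the wild type after Pst. On the wrky18 array, 13 genes were at least 2-fold higher and 44 at least 2-fold lower. Of these, 0 higher and 23 lower genes also differed at least 2-fold, in the same direction, from the median of the other mutant arrays. They included SPPA, a chloroplast protease gene, 2.84-fold lower, the beta-glucosidase gene BGLU33, 2.54-fold lower, VTC4, a gene of ascorbate synthesis, 2.34-fold lower, and the chloroplast-encoded ribosomal protein gene rpl33, 2.33-fold lower. In the simulated wrky53 comparison 24 of 12886 unchanged genes passed both counts. The 23 genes are thus no more than unchanged genes gave there. The direction split on this array depended on scaling: 16 higher and 23 lower with quantile normalization, 27 and 22 with median centring, and 18 and 35 with cyclic loess. The genes that also differed from the other mutants were then 1 higher and 10 lower, 1 and 12, and 2 and 14. With the lower floor the first counts were 118 and 155, and 33 higher and 84 lower genes also differed from the other mutants. On the wrky40 array, 8 genes were higher and 11 lower, the fewest of any pair of Pst arrays, and 12 and 10 with median centring. With the lower floor they were 183 and 65, so the direction of this split depended on the floor. QQS, a gene of starch metabolism, was at least 6.77-fold higher on this array, with a signal of 150 (149.5) against 21.6 on the wild-type Pst array. AT5G53750 was 2.76-fold lower and the lectin gene AT1G52000 2.24-fold lower. The immunity list had medians of 0.19 on the wrky18 array, at percentile 96.5, and -0.02 on the wrky40 array, at percentile 49.1.

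On the wrky53 array, the pattern-triggered immunity genes had lower signals than on the wild-type Pst array, with a median log2 ratio of -0.79 at percentile 0 of the random lists. PUB22 had a ratio of -1.72, WRKY22 -1.35, PUB23 -0.94 and BIK1 -0.65, EFR was at the floor on both arrays, and 2 of the 6 members were at least 2-fold lower. Among single genes, AT1G72060 was 5.51-fold lower, the peroxidase gene AT5G64100 4.53-fold lower, and the lipid transfer protein gene AT4G12500 4.31-fold lower. AT2G44370 and AT2G44380 were 4.16-fold and 3.95-fold lower, AT1G51850 3.96-fold lower and the pectin methylesterase gene ATPMEPCRB 3.57-fold lower. On the wrky60 array AT5G64100, AT4G12500 and AT2G44380 were low too, with signals of 33.3, 204 and 40.9. The wild-type Pst array had 110, 645 and 92.6 and the wrky53 array 24.2, 150 and 23.4. The other genes named here as lower were less than 2-fold below the wild type on the wrky60 array. Genes with higher signals included AT3G28270, 3.47-fold, AT1G68600, 2.71-fold, TBL26, 2.42-fold, and BSMT1, 2.08-fold. BSMT1 was also 2.21-fold higher on the wrky60 array, where the others did not reach 2-fold. In all, 17 genes were at least 2-fold higher on the wrky53 array and 67 at least 2-fold lower, of which 10 and 51 also differed from the median of the other mutants. With the lower floor 88 were higher and 139 lower, of which 25 and 82 also differed from the median of the other mutants.

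Relative to the wild-type Pst array, the double mutant showed the opposite direction for the immunity list. Against the mock array the list was still lower on the double mutant array, with all 6 members below 0. Its median there was -0.30 at percentile 2.93, which did not stand apart, against -0.87 for the wild type after Pst. AT1G26380, entered in the fixed list of camalexin and indole genes as FOX1, was 10.2-fold higher on the double mutant array than on the wild-type Pst array. AT4G16260, a glycosyl hydrolase gene, was 5.25-fold higher, AT2G35730 4.66-fold, the cytochrome P450 gene CYP71B24 4.23-fold, AT1G64710 4.14-fold and the calcium-binding protein gene AT5G39670 3.68-fold higher. QQS was at least 3.45-fold higher, as it was on the wrky40 array. Among lower genes, AT3G59780 was 3.21-fold and AT2G28605 2.57-fold lower. All these folds are against the wild-type Pst array, where AT1G26380 had a signal of 28.5, near the floor. On the double mutant array it had 291, and on the mock array 117. CYP71B24 had 114 and 93.7 on these arrays, but AT4G16260 801 and 38.8. In all, against the wild-type Pst array, 95 genes were at least 2-fold higher and 11 at least 2-fold lower, of which 68 and 2 also differed from the median of the other mutants. With the lower floor 185 were higher and 101 lower, of which 97 and 36 also differed from the median of the other mutants. The immunity list had a median of 0.50, at percentile 100 (99.98), with PUB24 at 0.63, BIK1 at 0.60, PUB22 at 0.53, EFR at 0.47 or higher, PUB23 at 0.41 and WRKY22 at 0.04, and 0 of 6 members reached 2-fold. The photosynthesis list had a median of -0.31, at percentile 0.325, with all 7 members below 0 and 0 at least 2-fold lower. SBPASE had a ratio of -0.51 and PRK -0.36, both genes of the Calvin cycle. The reference genes on the same array had a median of -0.22, at percentile 6.3, with 4 of 5 members below 0.

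**Figure D2:**
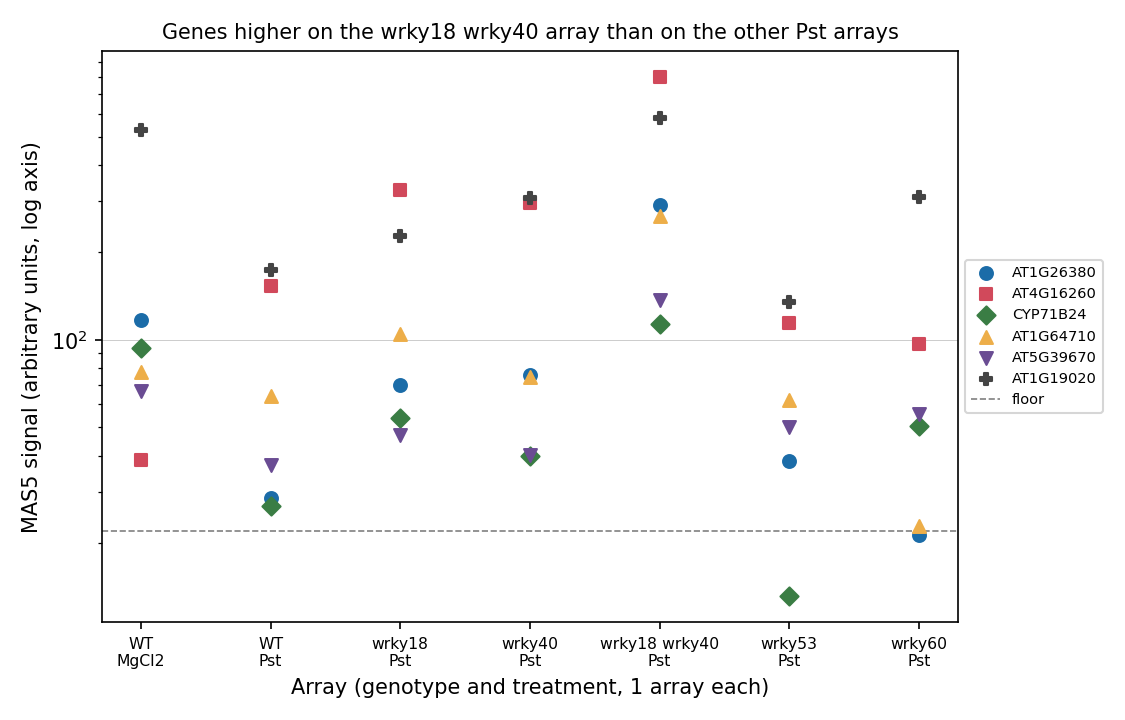
MAS5 signal on a log axis (arbitrary units) of 6 genes chosen for their higher signal on the array of the double mutant, on each of the 7 arrays, with the floor as a dashed line. AT1G26380 had a signal of 291 on that array, 70.0 on the wrky18 array, 76.0 on the wrky40 array and 28.5 on the wild-type Pst array.

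The double mutant was then set against each single mutant. It had 99 genes at least 2-fold higher and 25 at least 2-fold lower than the wrky18 array, and 54 and 15 against the wrky40 array. With the lower floor more genes were lower than higher against the wrky40 array, so the direction of that split depended on the floor. Against the wrky18 array more genes were still higher than lower with that floor. At least 2-fold beyond the wild type and both singles were 30 higher genes and 0 lower genes, but 46 and 18 with the lower floor. Measured against the higher single, AT1G26380 was 3.83-fold higher, AT4G19370 3.3-fold, AT5G52760 at least 2.92-fold, AT1G57630 2.91-fold and AT5G39670 2.90-fold. Over these 30 genes the median log2 ratio to the wild type was 1.62 on the double array, 0.03 on the wrky18 array and 0.20 on the wrky40 array, but they were chosen for exceeding both singles. Of the 95 genes higher on the double array, 8 were also at least 2-fold higher on the wrky18 array and 3 on the wrky40 array. All these lists share the wild-type Pst array, so they are not independent and the overlap does not by itself show a shared effect.

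The wrky60 array differed from the wild-type Pst array in more genes than any other, and its control probe sets differed too. On it, 852 genes were at least 2-fold higher and 313 at least 2-fold lower, of which 720 and 221 also differed from the median of the other mutants. The split was 548 and 487 with quantile normalization and 394 and 323 with cyclic loess, of which 448 and 359, and 299 and 224, also differed from the other mutants. With the lower floor it was 2293 and 709, of which 2030 and 563 also differed from the other mutants. The chloroplast-encoded genes psbM, of photosystem II, and psaB, of photosystem I, were 9.79-fold and 6.67-fold higher. Lower genes included the Golgi protein gene ATGRIP, 4.95-fold, and SPI, at least 4.17-fold. On the same array the bacterial spike-in probe sets had a median of 7.22-fold the other arrays, the 25S ribosomal RNA control a signal of 14546 against 1188 to 2947 elsewhere, and the 40th percentile of signal was 31.3 against at most 21.6 elsewhere.

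As a background for all mutant comparisons, the same 2-fold count was made for each pair of Pst arrays. Each pair differs in genotype, so these counts hold mutant effects as well as array and plant differences. The 10 pairs without the wrky60 array differed in 19 to 283 genes, with a median of 95, and the widest was wrky53 against the double mutant. Against the wild-type Pst array the counts were 57 for wrky18, 19 for wrky40, 84 for wrky53 and 106 for the double mutant. The wild-type Pst array against the mock array gave 277, below the 283 of the widest pair. Pairs with the wrky60 array, the mock array included, differed in 1115 to 1467 genes. Mutant effects relative to the shared wild-type Pst array correlated across the 7259 measured genes with Pearson r from 0.02, for wrky53 with the double mutant, to 0.48, for wrky40 with the double mutant. Unchanged mutants sharing that array gave 0.50 in simulation, a value fixed in advance because each gene has the same spread on every simulated array. The observed covariances of 0.002 to 0.046 lay below the simulated 0.12 (0.119), or 0.066 with the spread taken without the wrky60 array. Both simulated covariances hold real differences between genotypes in their spread. The simulation therefore cannot show whether mutants share effects. To share no array, the second mutant of a pair was compared with the mean of the remaining mutant arrays instead, both ways round. That mean holds mutant effects and, for pairs without wrky60, the wrky60 array, so it is no second wild type. In this way wrky40 and the double mutant had r of 0.15 and 0.21, wrky18 and wrky40 0.004 and -0.05, and wrky18 and the double mutant 0.13 and 0.14. The values were -0.15 and -0.26 for wrky53 and the double mutant, -0.24 and -0.11 for wrky53 and wrky18, and -0.21 and 0.02 for wrky53 and wrky40, so negative values were not particular to the double mutant. These are correlations across genes, which are not independent replicates.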

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

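All tests weighed in this part were chosen after values of these arrays had been seen, and those on scaling and on 3' to 5' ratios were also reworded after their first outcome was known.

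Genes lower after Pst, chosen from mutant arrays other than those compared, lay on opposite sides of the wild type, with a median log2 ratio of -0.46 on the wrky53 array (124 genes) and 0.31 on the double mutant array (170 genes), or 0.40 for the double mutant (154 genes) by the choice of genes fixed beforehand; the difference between the 2 arrays was not tested. A scaling difference of the whole array would move genes higher and lower after Pst alike, but the median of the higher genes minus that of the lower genes was 0.70 for wrky53 and -0.42 for the double mutant. For genes higher after Pst the median was 0.24 on the wrky53 array, which may therefore hold plants further along the whole response. On the double mutant array it was -0.11, so both medians met the limits set for plants less far along, and this array may hold such plants. The median of the higher genes did not set the double mutant apart, since wrky40 had -0.12 and wrky18 -0.06. The median of the genes lower after Pst did, at 0.31 against -0.04 for wrky40 and -0.01 for wrky18. With 1 array per genotype, a difference in inoculation or harvest and the loss of the WRKY genes would both give such shifts, and the latter stays open as untested.

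On the wrky60 array the bacterial spike-in probe sets, which no comparison used, had a median of 7.22-fold the other 6 arrays, and the 25S ribosomal RNA control a signal of 14546. Spike-ins are added in equal amount, so less plant target on this array, scaled up to the common mean, may account for their higher signals. Whether it accounts for the 25S ribosomal RNA signal or for the changed genes was not tested. Shorter target or poorer RNA stays open, since 4 of 6 control 3' to 5' ratios exceeded all other arrays and 2 did not. Loss of WRKY60 also stays open: of the genes higher on this array, 30.4% reached 2 times the floor on another array, against 46.3% of all genes, which falls between the limits set for either reading. The share cannot separate the readings, because loss of a transcription factor could also raise genes that are low on all other arrays.

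Signals were also seen in 2 probe sets with no named gene, outside the gene comparisons, that were low on arrays of lines sharing an insertion. The first had signals of 1.83 on the wrky18 array and 20.3 on the double mutant array, against 124 to 328 on the other Pst arrays and 189 on the mock array. The second had 11.7 on the wrky40 array and 16.5 on the double mutant array, against 231 to 310 (310.4) and 230.0 on the mock array. Each was the sole probe set of 22746 at least 2-fold below the other Pst arrays for its pair. They may measure the genes carrying the insertions. But the 8 pairs sharing no insertion gave 5 such probe sets, all for wrky60 with wrky53, so the test as set left this open. After the floor, the gap to the lowest other Pst array was 2.49 log2 for the first and 3.39 for the second. For those 5 it was at most 1.38.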

How the results depend on the processing

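With 1 array per group there was no error to test against, and the number of arrays and the signal over background limit what can be read. A count was taken as unmoved within 1.5 times, a correlation within 0.1, a list median within 1 SD of random-list medians and a single gene within 1.5-fold. By these limits 153 counts, 183 list medians, 84 correlations and 783 single-gene values stayed, and 125, 12, 2 and 78 moved, while no fixed list that stood apart and no named gene changed sign. Of the 2 medians of Pst-response genes on the double mutant array, 1 stayed and 1 moved, from 0.40 to 0.31 for the genes lower after Pst, when the genes were chosen on the median of the other mutants, an alternative added after seeing the data. Leaving out the wrky60 array, also added after seeing the data, gave 141 higher and 147 lower genes for the wild-type response, 14 and 49 for wrky18, 9 and 12 for wrky40, 18 and 71 for wrky53, and 99 and 14 for the double mutant. No paired analysis was possible because each group has 1 array. For all values below the cause was not tested, except that a lower floor lets in more low signals, a higher floor or an added constant shrinks ratios, and counting every probe set counts more items.

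Counts are given as higher and lower genes. With the floor at the 25th percentile they were 237 and 230 for the wild-type response, 118 and 155 for wrky18, 183 and 65 for wrky40, 2293 and 709 for wrky60, 88 and 139 for wrky53, 185 and 101 for the double mutant, and 46 and 18 for the double mutant beyond both singles. With the floor at the 60th percentile they were 77 and 83, 5 and 13, 1 and 4, 165 and 104, 8 and 38, and 48 and 3 in the same order, and 12 genes were higher beyond both singles. With log2 of signal plus the floor value they were 83 and 84, 3 and 6, 3 and 5, 205 lower for wrky60, 6 and 40, 55 and 3, and 17 and 1. With every probe set they were 317 and 277, 25 and 72, 20 and 23, 1389 and 575, 36 and 113, 216 and 32, and 79 and 1. Quantile normalization gave 23 lower for wrky18 and 548 and 487 for wrky60, median centring 27 and 22 for wrky18, and cyclic loess 394 higher for wrky60. Against the median of the other Pst arrays, 7 genes were higher on wrky18, 5 higher on wrky40 and 7 lower on the double mutant.

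The immunity list median was -0.70 for the wild-type response with log2 of signal plus the floor value. With the floor at the 60th percentile it was 0.31 for wrky18 and -0.94 for wrky53, and against the median of the other Pst arrays -0.93 for wrky53. The photosynthesis median was -0.11 with quantile normalization and -0.0324 with cyclic loess for wrky18, against 0.20 with the deposited scaling, a change of sign in a list that had not stood apart, -0.10 with quantile normalization for wrky40, and 0.13 against the other Pst arrays for wrky53. The reference gene median against the other Pst arrays was 0.0190 for wrky18, 0.00325 for wrky40, -0.00325 for wrky53 and -0.0771 for the double mutant, where it was -0.13, -0.20, -0.12 and -0.22 against the wild type. With the floor at the 25th percentile the correlations of wrky53 with wrky18 and with the double mutant were 0.175 and 0.154, and WRKY53 on the wrky53 array had a log2 ratio of -3.69 or lower, against -0.82 or lower with the floor at the 60th percentile, since its signal lay below both floors.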

Other observations

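Chloroplast-encoded transcripts, a group chosen after the data were seen, differed between arrays. Of 67 measured chloroplast genes, 43 were at least 2-fold higher on the wrky60 array than on the wild-type Pst array, with a median log2 ratio of 1.28, on the array whose control probe sets also differed. The median was 0.41 on the wrky18 array, 0.08 on the wrky40 array, 0.06 on the double mutant array, -0.03 on the wrky53 array and -0.14 for the wild type after Pst against mock.

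Of the single members of short lists, WRKY6, a gene linked to senescence, had log2 ratios to the wild-type Pst array of 1.12 on the double mutant array and -0.78 on the wrky53 array. STZ (ZAT10), a zinc finger gene of stress responses, had 0.89 and -0.40 on these arrays. BCAT4, of aliphatic glucosinolate synthesis, had the opposite pattern, with -0.51 and 0.53. These sides were not particular to the 2 arrays. On the wrky60 array WRKY6, STZ and BCAT4 lay on the wrky53 side, at -0.65, -0.90 and 0.42. On the wrky18 array they lay on the double mutant side, at 0.24, 0.32 and -0.43, as on the wrky40 array, at 0.44, 0.47 and -0.18. The senescence marker SAG29 was below the floor on all 7 arrays, as were the clock gene GI, the root marker EXPA7 and the meristem marker CLV3. Of the 95 genes higher on the double mutant array, 62 had a higher mock signal than the median of the single mutant arrays other than wrky60, and 60 of the 67 genes lower on the wrky53 array had a higher mock signal than the median of wrky18, wrky40 and the double mutant, against 47.9% and 51.8% of measured genes for the matching medians.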
